A study of Homo sapiens with 4 samples.

How the data were processed

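RNA from HCT116 cells was measured on 4 Agilent dual-channel gene expression arrays. HCT116 is an established human colorectal carcinoma line, and the cells carried Fucci, a fluorescent reporter that is red in G1 and green in S, G2 and M phase. Per the labels, R is the red fraction taken at a first flow cytometric sort. RR is the fraction that was still red after the R cells had been cultured for another 12 h and sorted again. Each array held R in one channel and RR in the other. The labels name 2 biological replicates, each hybridised in both dye orientations, so that the dye-swapped arrays of a replicate were technical repeats and n was 2. The labels do not say whether the 2 replicates came from separately kept cultures. If they did not, the p-values measure only the spread between these samples.

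The scanner tables hold each spot's brightness as an intensity in the Cy3 and Cy5 channels, with a local background, per the file headers. The same tables hold a log10 ratio of red over green computed by the scanner software after its own background subtraction and dye normalization, per the file headers. The series matrix deposited by the authors also holds a log10 ratio. Set against the scanner's log10 ratio of the same array, its columns gave a correlation of 0.999999 or -0.999999, with a largest difference of 0.00495 after the sign was turned. Its values were therefore RR over R, with a median of 0 in every column. The flags used for filtering are yes-or-no entries of the scanner software, per the file headers. The headers name Feature Extraction version 10.7.3.1, whereas the submitters' processing notes name version 10.5.1.1. Probe coordinates in the files are on human genome build hg18 and were printed as the files give them. Slide and scan time did not vary, since the headers showed 1 slide and 1 scan time, so a slide effect could not be fitted.

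Of 44495 spots on each array, 43118 were not controls, and they carried 34127 distinct probes. Signals were background-corrected with normexp at an offset of 50, fitted on all spots, and normalized within each array by loess with control and outlier-flagged spots at weight 0. Each log2 ratio was turned to RR over R from the dyes in the labels, and spots of 1 probe were averaged. A probe was kept if it was well above background on all 4 arrays in R or on all 4 arrays in RR, with at least 0.5 of its spots passing on an array. This left 19993 probes, after 4 more had been lost to outlier flags. For a gene with several probes the brightest was used, a choice made for 3292 genes, and where another probe of a named gene differed from it by more than 0.5 on the log2 scale or in sign, its value is given. In all, 16064 genes were tested, of which 15453 were above background in both populations and 611 reached the filter in only 1 of them. Some of those 611 were still well above background on part of the other population's arrays. A gene that was below background on all 4 arrays of a population was given a bound, as "at least N-fold", from the mean normalized log2 signal of the brighter population. The dimmer population was set to the higher of its own signal and the lowest signal among probes well above background on that array.

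Gene names were taken from a RefSeq gene list of assembly GRCh38.p14, used for names alone and for no coordinate. Among tested genes, 12991 were matched by accession, 411 by symbol and 152 by an older symbol, and 2510 kept the name in the array files. Genes are those of the array design, and near-identical copies that could share a probe's signal are stated as uncertain.

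The 2 dye-swapped arrays of each replicate were averaged, and the 2 replicate means were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, against a log2 ratio of 0, two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Adjusted p-values of genes throughout are from this limma fit. With 1 residual degree of freedom per gene, the spread came mainly from a prior shared by all genes, with an estimated 20.0 degrees of freedom and an SD of 0.0872. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 22 lists, with camera at an estimated correlation and fry beside it. With 1 residual degree of freedom, camera at an estimated correlation could hardly call a list, so its lack of calls decides nothing. Files were read with version 1.17.8 of data.table and version 2.0.0 of jsonlite.

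The 22 lists were G1/S and replication (E2F) genes, G2/M and mitosis genes, replication-dependent histones, G1 regulators and CDK inhibitors, p53 targets, FoxO-linked and quiescence-linked genes, immediate early genes, NF-kB targets and cytokines, interferon-stimulated genes, and heat shock genes. The others were integrated stress and unfolded protein response genes, hypoxia and glycolysis genes, cholesterol synthesis, ribosome biogenesis and MYC-linked genes, Wnt targets, intestinal differentiation markers, TGF-beta and matrix genes, lysosome and autophagy genes, the BCL2 family, mitochondrial respiration, leukocyte and fibroblast markers, and housekeeping genes. A list's direction was read with its members' calls.

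The groups, the test, the lists, the rule for named genes and most other settings compared were set before the data were examined. The rule named the 12 called genes with the largest and the 12 with the smallest log2 ratio among officially named genes above background in both populations and moving the same way on all 4 arrays. It also named up to 4 called members of each list by size of change, 21 cell cycle regulators and related genes whatever their result, and the 6 brightest genes measured in 1 population alone. Members of a list named because they were among the few that went the other way were chosen after their values were seen. Some genes that the rule names are not reported here.

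The fit was tested on simulated data with 200 genes changed among 16064, in 20 simulations of the comparison of RR with R. It recovered 91.5% of genes changed by 1.25-fold and 100% of those changed by 1.5-fold, 2-fold or 4-fold. False calls made up 10.9% of calls, above the nominal level, because the prior degrees of freedom were poorly estimated from 1 residual degree of freedom and came out infinite in 8 of the 20 simulations. With the prior known, false calls were 5.19% of calls. With 8682 genes changed, as many as were called in the data, false calls were 2.57% of calls and 90.2% of changed genes were recovered. The simulated changes were the log ratios measured for the called genes, and all other genes were left unchanged. Noise was drawn separately for each gene from the fitted prior. Small true changes and correlation between genes were therefore not simulated, which favours few false calls and a high recovery. The 2.57% is not an error rate for the calls in the data.

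Median raw signals were 112 to 138 in Cy3 and 164 to 229 in Cy5, over median backgrounds of 20.5 to 22 and 39 to 40. No spot was saturated, and 370 to 415 spots per array carried an outlier flag. The number of arrays limits the precision.

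Alternatives covered the background correction, the normalization, the scanner's own log ratio, the deposited series table, the filter on dim probes, the choice among probes, the treatment of replicates and arrays, a minimum change, the prior variance and the gene list test. Fits with each gene's own spread, the workable forms of the replicate block, and lists without each array were added after seeing the data.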

Results

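Gene expression was compared between G1 cells of the HCT116 colorectal carcinoma line that had just been sorted (R) and cells of the same sort that were still in G1 after a further 12 h of culture and a second sort (RR). Both populations were red for the Fucci reporter. Per the labels the design addressed G1 arrest and its maintenance, by setting long-term arrested cells against G1 cells. Each of 2 biological replicates was hybridised on 2 dye-swapped arrays, making 4 arrays, and every ratio below is RR over R. Between 62.6% and 64.8% of spots were well above background in R and between 61.8% and 64.1% in RR, and the number of arrays limits the precision. Log2 ratios are given as the mean ± SD over the replicate means, n = 2.

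The largest increase in RR among genes above background in both populations was that of SBSN, which encodes the epidermal protein suprabasin. Its log2 ratio was 3.10 ± 0.15 (8.60-fold, n = 2, limma adjusted p = 4.2e-19), from a probe on chromosome 19 at 40706112 to 40706171 of hg18. The stress-responsive GADD45G rose by 2.70 ± 0.39 (chromosome 9, 91411220 to 91411279) and GADD45B by 2.22 ± 0.22, and the heme-degrading enzyme HMOX1 rose by 2.47 ± 0.18 (chromosome 22, 34120122 to 34120181). The transcription factor JUN (1.94 ± 0.20, chromosome 1, 59019099 to 59019158) and the chemokine CXCL1 (2.05 ± 0.56) were also among the 12 largest increases. ARL14, a small GTPase of the ARF-like family (2.47 ± 0.05), TRIML2 (1.94 ± 0.08), RFPL4A (2.02 ± 0.13) and the keratin-associated KRTAP3-2 (2.62 ± 0.05) and KRTAP4-1 (1.77 ± 0.18) were others of them. A second probe gave 1.39 for GADD45G, 0.92 for CXCL1 and 0.50 for KRTAP4-1, so that the sizes for these genes depended on the probe.

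Among the 12 largest decreases were 4 cell cycle genes or their relatives and 5 small noncoding RNAs. Cyclin B2 (CCNB2) fell by 1.37 on the log2 scale (SD 0.25, n = 2, limma adjusted p = 2.3e-12, chromosome 15, 57204431 to 57204490), and securin (PTTG1) had a log2 ratio of -1.35 ± 0.13. PTTG2 (-1.46 ± 0.11) and PTTG3P (-1.13 ± 0.05), the latter chosen after its value was seen, are near-identical to PTTG1, and their own changes are uncertain. PRR11, a cell cycle-linked gene, gave -1.31 ± 0.31. The small RNAs were the U3 snoRNA gene SNORD3B-1 (-2.77 ± 0.08, chromosome 17, 18908088 to 18908147), SCARNA16 (-1.85 ± 0.15), SNORA12 (-1.68 ± 0.33), the RNase MRP RNA RMRP (-1.81 ± 0.72) and SNAR-A3 (-1.54 ± 0.45). Near-identical copies exist for SNORD3B-1 and SNAR-A3, which makes the source of their signal uncertain, and RMRP differed between replicates, at -1.30 and -2.32. The other decreases were those of the helix-loop-helix inhibitor ID1 (-1.49 ± 0.01), the GTPase RAB26 (-1.56 ± 0.05) and the retinal reductase DHRS3 (-1.32 ± 0.14). With an intensity trend in the prior variance, the call of SNORD3B-1 ended (adjusted p = 0.235).

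Across 16064 genes tested, 4193 were higher and 4489 lower in RR and 7382 were not called. Changes were mostly small: the median absolute log2 ratio of called genes was 0.29, and 90.6% of them were under 1.5-fold. At 1.5-fold or more, 442 genes were higher and 377 lower, and at 2-fold or more 84 and 43. Of the 8682 called genes, 7999 moved the same way on all 4 arrays. Across genes, which are not independent replicates, the means of the replicates correlated at r = 0.907, the dye-swapped arrays of a replicate at 0.808 and 0.807, and arrays of the same dye orientation from different replicates at 0.907 and 0.884. A gene-specific dye effect with an SD of 0.0956 on the log2 scale was called for 5846 genes and cancels in each replicate's mean. The calls rest on a spread shared by all genes: with each gene's own spread alone none passed the adjusted threshold and 3092 had an unadjusted p under 0.05, against 9491 with the shared spread. When arrays were centred on their median instead of normalized by loess, 59.9% of calls were higher in RR, against 48.3%. Among genes named below that centring ended the calls of CDKN1C (-0.14, adjusted p = 0.0787), DDB2 (-0.14, adjusted p = 0.0778), FDXR (-0.06, adjusted p = 0.496), NDUFB3 (-0.14, adjusted p = 0.0840) and HSPD1 (-0.07, adjusted p = 0.434). It also ended those of TNFAIP2 (-0.05, adjusted p = 0.602), CAD (-0.10, adjusted p = 0.240), H2AC6 (-0.16, adjusted p = 0.0507), H3C1 (-0.09, adjusted p = 0.310) and GUSB (-0.12, adjusted p = 0.163). CCND3 (0.22, adjusted p = 0.00557) and CCNE2 (0.22, adjusted p = 0.00441) were called under it alone. In the scanner's own log ratio some genes had larger values, ARL14 being at 3.81, RFPL4A at 3.21 and CRYAB at 2.60. Of 178 called genes chosen for naming, 26 moved by more than 1.5 times in that log ratio, 20 under median centring, 17 with an offset of 0 and 10 with the mean over a gene's probes.

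**Figure D1:**
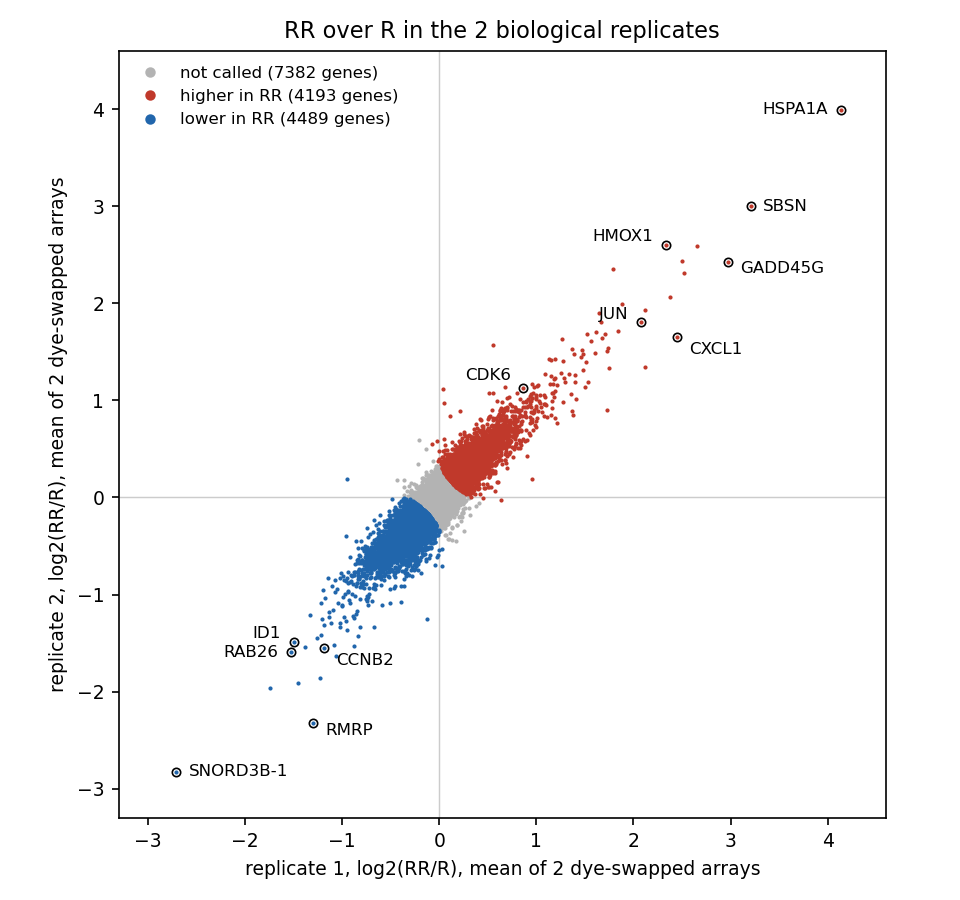
Log2 ratio of RR over R for each gene tested in biological replicate 1 (horizontal axis) and replicate 2 (vertical axis), each the mean of its dye-swapped arrays, with red for higher, blue for lower and grey for not called, and some named genes circled. The replicate means correlated at r = 0.907 across genes, with SBSN at 3.10 and SNORD3B-1 at -2.77 on average.

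Only in RR were 40 genes measured and only in R 35, being below background on all 4 arrays of the other population. The bounds were low, at 1.13-fold to 3.08-fold for the 40 genes, all called, and 1.02-fold to 1.31-fold for the 35, of which 27 were called. The brightest was TGFBI, an extracellular matrix protein induced by TGF-beta, which was at least 3.08-fold higher in RR (limma adjusted p = 2.8e-15). INHBA, which encodes the activin A subunit, was at least 1.83-fold higher and the muscle-linked MLIP at least 1.44-fold. For INHBA and MLIP the bound was the measured ratio itself, since their own signal in R was used. Unnamed transcripts in the same class were LOC729083 (at least 1.88-fold), LOC100129236 (at least 1.63-fold) and BG188151 (at least 1.54-fold). The sizes for these genes depended on the processing. Their log2 ratios ran from 0.53 for MLIP to 1.78 for TGFBI in the main fit. The highest values in other settings ran from 1.70 for MLIP to 4.65 for TGFBI, with LOC729083 at 3.95 and INHBA at 2.50. The lowest ran from 0.45 for MLIP to 1.72 for TGFBI, with INHBA at 0.83, LOC100129236 at 0.67 and BG188151 at 0.61. The bounds are therefore not lower limits over all settings. The heat shock gene HSPA1A had a log2 ratio of 4.06 ± 0.10, and it was well above background on all 4 arrays in RR and on 3 of 4 in R. With R this near background the size was uncertain, and it was 5.93 in the scanner's log ratio. An intensity trend in the prior variance ended its call (adjusted p = 0.107). Its near-identical copy HSPA1B, on another probe, rose by 1.11 ± 0.37, so the 2 copies cannot be separated with certainty.

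Both populations were gated as G1. Of 57 measured G2/M and mitosis genes, 35 fell and 5 rose (35 and 6 adjusted over the list alone), with a median log2 ratio of -0.25. The largest falls, besides CCNB2 and PTTG1, were those of the checkpoint kinase BUB1 (-1.16 ± 0.19) and the spindle protein DLGAP5 (-1.11 ± 0.17). Cyclin B1 (CCNB1) gave -1.03 ± 0.24 on its brightest probe and -0.35 on another, and the proliferation marker MKI67 gave -0.41 ± 0.16 and -0.08. The 5 members that rose, chosen after their values were seen, were UBE2C (0.32 ± 0.36), CDCA8 (0.30 ± 0.28), HJURP (0.29 ± 0.10), KIF23 (0.28 ± 0.11) and KIF18A (0.23 ± 0.03). The KIF18A call ended without the replicate 1 array with RR in Cy5 (log2 ratio 0.16, adjusted p = 0.119) and without that of replicate 2 (0.20, adjusted p = 0.0535). Cyclin A2 (CCNA2) was at 0.01 ± 0.15 (adjusted p = 0.927). The list shifted down by camera (adjusted p = 7.5e-07), with adjusted p = 0.783 with an estimated correlation, a form that could hardly call any list here. Its median was -0.17 in replicate 1 and -0.41 in replicate 2.

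Of 47 G1/S and replication genes, 30 fell and 4 rose (31 and 4 adjusted over the list alone), with a median of -0.22 that was -0.11 under median centring. The falls included the DNA primase subunit PRIM1 (-0.73 ± 0.05), the helicase component GINS4 (-0.69 ± 0.02) and the polymerase epsilon subunit POLE2 (-0.63 ± 0.10). Those that rose were cyclin E1 (CCNE1, 0.33 ± 0.00) and, chosen after their values were seen, CDC25A (0.23 ± 0.08), GINS3 (0.21 ± 0.05) and RRM2 (0.17 ± 0.07). RRM2 lost its call without the replicate 1 array with RR in Cy5 (log2 ratio 0.05, adjusted p = 0.669) and without that of replicate 2 (0.11, adjusted p = 0.303), and GINS3 without the arrays with RR in Cy3 of replicate 1 (0.17, adjusted p = 0.0752) and replicate 2 (0.16, adjusted p = 0.0879). E2F1 gave -0.35 ± 0.02, cyclin E2 (CCNE2) 0.11 ± 0.12 (adjusted p = 0.133) and the licensing factor CDT1 -0.07 ± 0.11 (adjusted p = 0.389), and geminin (GMNN), the inhibitor of CDT1, fell by 0.45 on the log2 scale (SD 0.04, n = 2). The list shifted by camera (adjusted p = 1.3e-06), with adjusted p = 0.594 with an estimated correlation.

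Replication-dependent histones did not shift as a list: 10 of 29 rose and 4 fell (10 and 4 adjusted over the list alone), with a median of 0.01 and a camera adjusted p of 0.395. H2BC12 rose by 0.95 ± 0.09 (0.30 on another probe), H2BC14 by 0.33 ± 0.16 and H2BC5 by 0.32 ± 0.25. The falls were those of H4C8 (-0.32 ± 0.42) and, chosen after their values were seen, H4C1 (-0.30 ± 0.41), H2AC6 (-0.25 ± 0.39) and H3C1 (-0.20 ± 0.05). Of these H4C8, H4C1 and H2AC6 did not have the same sign on all 4 arrays. H2AC6 was at 0.96 on another probe and turned to 0.22 when its probes were averaged. The call of H3C1 ended without the arrays with RR in Cy5 of replicate 1 (-0.18, adjusted p = 0.0630) and replicate 2 (-0.17, adjusted p = 0.108). The list median was 0.22 in replicate 1 and -0.14 in replicate 2, and 0.11 under median centring.

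Regulators of G1 moved in both directions. CDK6 rose by 1.00 ± 0.18 (chromosome 7, 92072379 to 92072438, adjusted p = 1.2e-10), the CDK inhibitor p21 (CDKN1A) by 0.54 ± 0.09 (chromosome 6, 36760156 to 36760215, adjusted p = 2.9e-07), cyclin D1 (CCND1) by 0.53 ± 0.07 and MYC by 0.55 ± 0.20. SKP2, the ubiquitin ligase subunit that targets p27, fell by 0.58 on the log2 scale (SD 0.03, n = 2), and p27 itself (CDKN1B) rose by 0.25 ± 0.13. The other CDK inhibitors CDKN1C (-0.26 ± 0.00) and CDKN2C (-0.28 ± 0.10), the retinoblastoma gene RB1 (-0.32 ± 0.03) and its relative RBL2 (-0.45 ± 0.07) fell. CDK2 gave -0.19 ± 0.05 (adjusted p = 0.0123), CDK4 0.16 ± 0.00 (adjusted p = 0.0302) and CCND3 0.13 ± 0.16 (adjusted p = 0.112). CDK2 lost its call without the arrays with RR in Cy5 of replicate 1 (-0.17, adjusted p = 0.0805) and replicate 2 (-0.16, adjusted p = 0.128). CDK4 lost its call without any 1 of the 4 arrays, at log2 ratios of 0.14 to 0.18 and adjusted p of 0.0521 to 0.172. Of 29 measured members 12 rose and 9 fell (12 and 9 adjusted over the list alone), and the list as a whole did not shift (median 0.11, being 0.14 in replicate 1, 0.08 in replicate 2 and 0.04 without genes of more than 1 list, camera adjusted p = 0.395).

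**Figure D2:**
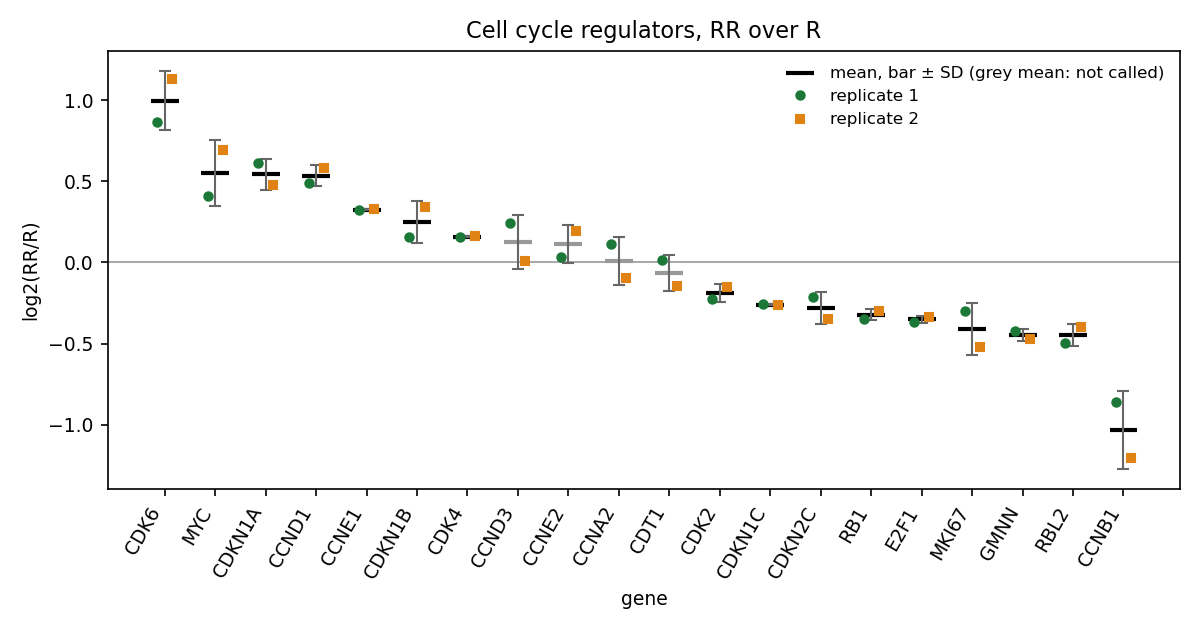
Log2 ratio of RR over R (axis in log2 units) of named cell cycle regulators, with a point for each replicate, a horizontal bar at their mean (grey where the gene was not called) and a vertical bar of ± SD, n = 2. CDK6 at 1.00 and CDKN1A at 0.54 lie above 0, and CCNB1 at -1.03 and GMNN at -0.45 lie below it.

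Of 38 measured targets of p53, 26 were higher and 4 lower (26 and 4 adjusted over the list alone), with a median of 0.35. Besides CDKN1A, the kinase PLK2 (1.43 ± 0.06), the death receptor FAS (0.85 ± 0.14), the nuclease AEN (0.74 ± 0.01) and TIGAR (0.70 ± 0.01), a regulator of glycolysis, led the list. The 4 lower members, chosen after their values were seen, were KITLG (-0.54 ± 0.13), CCNG1 (-0.27 ± 0.11), DDB2 (-0.26 ± 0.00) and FDXR (-0.19 ± 0.03), the last losing its call without the arrays with RR in Cy5 of replicate 1 (-0.15, adjusted p = 0.135) and replicate 2 (-0.16, adjusted p = 0.118). KITLG did not have the same sign on all 4 arrays, and was at -0.27 without the replicate 1 array with RR in Cy3 and -0.28 without that of replicate 2. By camera the targets shifted up (adjusted p = 1.4e-06), with adjusted p = 0.757 with an estimated correlation.

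Immediate early genes gave the list with the smallest camera p, 22 of 28 being higher and 2 lower in RR (22 and 2 adjusted over the list alone) at a median of 0.55. JUN was followed by the matricellular factor CCN2 (1.74 ± 0.10), FOSB (1.74 ± 0.55) and ATF3 (1.60 ± 0.12), of which ATF3 gave -0.03 on another probe. The 2 that fell, chosen after their values were seen, were DUSP6 (-0.53 ± 0.30) and SPRY4 (-0.33 ± 0.12), both feedback inhibitors of ERK signalling. The upward shift had a camera adjusted p = 2.1e-10, and adjusted p = 0.594 with an estimated correlation. Among NF-kB targets and cytokines, 16 of 21 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.54 that was 0.24 without the filter on dim probes. With CXCL1 rose interleukin 8 (CXCL8, 1.18 ± 0.13), the apoptosis inhibitor BIRC3 (1.11 ± 0.11) and the NF-kB subunit RELB (1.07 ± 0.02), and TNFAIP2 gave -0.16 ± 0.09, chosen after its value was seen. TNFAIP2 was no longer called without the replicate 1 array with RR in Cy3 (-0.13, adjusted p = 0.161) or without either array of replicate 2 (RR in Cy5, -0.19, adjusted p = 0.0694; RR in Cy3, -0.14, adjusted p = 0.141). For this list camera gave adjusted p = 7.1e-08, and adjusted p = 0.594 with an estimated correlation.

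Heat shock genes rose in 10 of 21 cases and fell in 2 (10 and 4 adjusted over the list alone), with a median of 0.14 that was 0.20 in replicate 1, 0.10 in replicate 2, 0.25 under median centring and 0.06 with the mean over a gene's probes. HSPA1A and HSPA1B, the small heat shock protein CRYAB (1.54 ± 0.08) and the co-chaperone HSPH1 (1.13 ± 0.33) led the increases. HSP90AA1 (-0.67 ± 0.02) and HSPD1 (-0.21 ± 0.13) fell and were chosen after their values were seen. HSPD1 did not have the same sign on all 4 arrays and was at -0.08 without the arrays with RR in Cy3 of replicate 1 (adjusted p = 0.432) and replicate 2 (adjusted p = 0.459). The heat shock list shifted up (camera adjusted p = 0.00367), with adjusted p = 0.594 with an estimated correlation. Integrated stress and unfolded protein response genes split, with 10 of 34 higher and 14 lower (10 and 16 adjusted over the list alone). The phosphatase subunit PPP1R15A (1.32 ± 0.26), the cystine transporter SLC7A11 (1.06 ± 0.72) and the transcription factor ATF4 (0.68 ± 0.22) rose, whereas the endoplasmic reticulum chaperone HSP90B1 fell by 0.69 on the log2 scale (SD 0.01, n = 2). SLC7A11 was at 0.55 in replicate 1 and 1.57 in replicate 2. That list's median was -0.12 (-0.12 in replicate 1, 0.0095 in replicate 2 and -0.02 under median centring) and its mean 0.01, and it did not shift (camera adjusted p = 0.782).

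Of 25 measured cholesterol synthesis genes, 21 were lower and 2 higher (21 and 2 adjusted over the list alone), with a median of -0.42. INSIG1, a sterol-sensing regulator (-1.10 ± 0.10), and squalene synthase FDFT1 (-0.88 ± 0.03) were among those that fell most. The 2 that rose, chosen after their values were seen, were HMGCS1 (0.33 ± 0.02) and PMVK (0.16 ± 0.11), the latter not called without the arrays with RR in Cy3 of replicate 1 (0.11, adjusted p = 0.246) and replicate 2 (0.10, adjusted p = 0.294). The fall had a camera adjusted p = 7.1e-08, and adjusted p = 0.594 with an estimated correlation.

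Genes of ribosome biogenesis rose in 20 of 34 cases and fell in 1 (21 and 2 adjusted over the list alone), with a median of 0.18 that was 0.30 under median centring. The nucleolar factors RRP12 (0.68 ± 0.01), NOP2 (0.60 ± 0.12), RRS1 (0.56 ± 0.02) and UTP20 (0.56 ± 0.05) rose most, and the pyrimidine synthesis gene CAD fell (-0.22 ± 0.10, chosen after its value was seen). Without the replicate 1 array with RR in Cy3, CAD was at -0.18 (adjusted p = 0.0573). Camera gave adjusted p = 8.6e-05, and adjusted p = 0.594 with an estimated correlation. Mitochondrial respiration genes fell in 12 of 29 cases and rose in 0 (11 and 0 adjusted over the list alone), with a median of -0.13. They included UQCRC2 (-0.47 ± 0.04), SDHA (-0.33 ± 0.03) and NDUFB3 (-0.26 ± 0.06). For them camera gave adjusted p = 0.00495, and adjusted p = 0.594 with an estimated correlation. Under median centring their median was -0.013 (adjusted p = 0.216), and without the replicate 1 array with RR in Cy5 the call also ended (adjusted p = 0.0650).

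In the BCL2 family 9 of 16 measured members rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.24 that was 0.19 in replicate 1, 0.30 in replicate 2 and 0.13 without genes of more than 1 list. The pro-apoptotic genes PMAIP1 (1.28 ± 0.21), BIK (0.91 ± 0.05), BAK1 (0.59 ± 0.08) and BCL2L11 (0.55 ± 0.13) rose most, with another probe of BCL2L11 at -0.17, and the pro-apoptotic HRK fell (-0.31 ± 0.12, chosen after its value was seen). Camera gave adjusted p = 0.00287, and adjusted p = 0.627 with an estimated correlation. Of 19 TGF-beta and matrix genes 11 rose and 5 fell (11 and 5 adjusted over the list alone), with a median of 0.20 that was 0.12 without the filter on dim probes. Besides TGFBI, the laminin chain LAMA3 (1.70 ± 0.02) rose. Those that fell were ID1 and, chosen after their values were seen, ID3 (-0.64 ± 0.18), SMAD6 (-0.53 ± 0.00), SMAD7 (-0.33 ± 0.05) and ITGB4 (-0.51 ± 0.09), of which ID1, ID3, SMAD6 and SMAD7 are known targets of BMP or TGF-beta signalling. For this list camera's adjusted p = 0.0460, and adjusted p = 0.627 with an estimated correlation. Its call ended without the replicate 2 array with RR in Cy3 (adjusted p = 0.0586) and when only genes above background in both populations were kept (adjusted p = 0.164), as well as with an offset of 0 (adjusted p = 0.0510) and with the mean over a gene's probes (adjusted p = 0.0775).

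FoxO-linked and quiescence-linked genes rose in 12 of 25 cases and fell in 4 (12 and 4 adjusted over the list alone), with a median of 0.13, being 0.06 in replicate 1, 0.19 in replicate 2 and 0.23 under median centring. The transcription factors KLF6 (0.88 ± 0.08, but 0.00 on another probe) and BCL6 (0.76 ± 0.18), the co-activator CITED2 (0.83 ± 0.19, and 0.18 on another probe) and the antiproliferative BTG1 (0.79 ± 0.28) rose. HES1 (-0.56 ± 0.30), KLF9 (-0.54 ± 0.24), FOXO1 (-0.49 ± 0.08) and TSC22D3 (-0.28 ± 0.09) fell and were chosen after their values were seen. Camera gave adjusted p = 0.0378, and adjusted p = 0.783 with an estimated correlation. With the scanner's own log ratio the call ended (adjusted p = 0.0881), as it did with an offset of 0 (adjusted p = 0.0679) and the 4 arrays taken as independent (adjusted p = 0.0632). The mean over a gene's probes also ended it, with a median of 0.07 (adjusted p = 0.133).

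The remaining lists did not shift. Of 24 interferon-stimulated genes 4 rose and 8 fell (4 and 8 adjusted over the list alone), with a median of -0.02 that turned to 0.04 under median centring (camera adjusted p = 0.782). IFIT2 (0.75 ± 0.06) and ISG20 (0.40 ± 0.06), with IFIT3 (0.33 ± 0.04) and OASL (0.33 ± 0.10) chosen after their values were seen, were higher, and IRF7 (-0.58 ± 0.05) and IRF9 (-0.53 ± 0.01) were lower. Hypoxia and glycolysis genes numbered 6 higher and 8 lower of 28 (6 and 8 adjusted over the list alone), with a median of -0.04 that turned to 0.09 under median centring, was 0.0081 in replicate 1 and -0.06 in replicate 2, and a mean of 0.04 (camera adjusted p = 0.913). The vasodilator peptide ADM (1.55 ± 0.29) and the glucose transporter SLC2A1 (0.76 ± 0.11) rose, and BNIP3L (-0.64 ± 0.17) and ENO2 (-0.52 ± 0.09) fell. Of 31 lysosome and autophagy genes 7 rose and 8 fell (7 and 8 adjusted over the list alone), with a median of 0.01 that was -0.00391 in the scanner's log ratio, -0.0021 in replicate 1, 0.03 in replicate 2 and 0.11 under median centring (camera adjusted p = 0.679). The autophagy genes SQSTM1 (0.81 ± 0.04), MAP1LC3B (0.71 ± 0.07) and GABARAPL1 (0.65 ± 0.08) rose and the lysosomal protease CTSB (-0.76 ± 0.08) fell.

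Wnt target genes numbered 7 higher and 2 lower of 15 (7 and 3 adjusted over the list alone; median 0.11, camera adjusted p = 0.267), with CD44 (0.78 ± 0.20) and SOX9 (0.76 ± 0.20) higher beside MYC and CCND1. The Wnt median was 0.05 in replicate 1, 0.11 in replicate 2 and 0.22 under median centring, and it turned to -0.06 without genes of more than 1 list. TCF7 (-0.41 ± 0.06) and RNF43 (-0.35 ± 0.02) fell and were chosen after their values were seen. Of 28 listed intestinal differentiation markers only 11 were measured, the others having failed the background filter or been flagged. The measured markers were mixed, 4 of 11 being higher and 3 lower (4 and 5 adjusted over the list alone), with a median of -0.06, a mean of 0.08 and a camera adjusted p of 0.747. Their median was 0.07 in replicate 1, -0.17 in replicate 2 and -0.15 in the scanner's log ratio. KRT80 (1.03 ± 0.04), AQP3 (0.52 ± 0.08), KRT20 (0.41 ± 0.02) and CDX2 (0.26 ± 0.01) rose, and DPP4 (-0.50 ± 0.16), CA2 (-0.37 ± 0.01) and MUC2 (-0.15 ± 0.06) fell, with CDX2, CA2 and MUC2 chosen after their values were seen. MUC2 was at 0.06 on another probe, and was not called without the replicate 1 array with RR in Cy3 (-0.09, adjusted p = 0.358) or either array of replicate 2 (RR in Cy5, -0.13, adjusted p = 0.190; RR in Cy3, -0.16, adjusted p = 0.0914). Leukocyte and fibroblast markers, which are foreign to the line, numbered 2 higher and 4 lower of 8 (2 and 4 adjusted over the list alone), with a median of -0.17 (-0.12 in replicate 1, -0.18 in replicate 2, -0.27 in the scanner's log ratio and -0.04 without the filter on dim probes), a mean of 0.01 and a camera adjusted p of 0.782. CD14 (0.94 ± 0.01) and CSF1R (0.25 ± 0.03) were higher, and COL1A1 (-0.34 ± 0.26), CD3D (-0.27 ± 0.01) and PDGFRB (-0.25 ± 0.07) were among the lower, with CSF1R chosen after its value was seen. Of 17 housekeeping genes 8 rose and 4 fell (8 and 4 adjusted over the list alone; median 0.08, camera adjusted p = 0.395). That median was 0.12 in replicate 1, 0.07 in replicate 2 and 0.22 under median centring, and it turned to -0.01 without either array with RR in Cy5. TFRC (0.53 ± 0.01) and POLR2A (0.35 ± 0.07) were among those that rose, and HPRT1 (-0.41 ± 0.10), SDHA and GUSB (-0.23 ± 0.04), the last chosen after its value was seen, among those that fell.

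**Figure D3:**
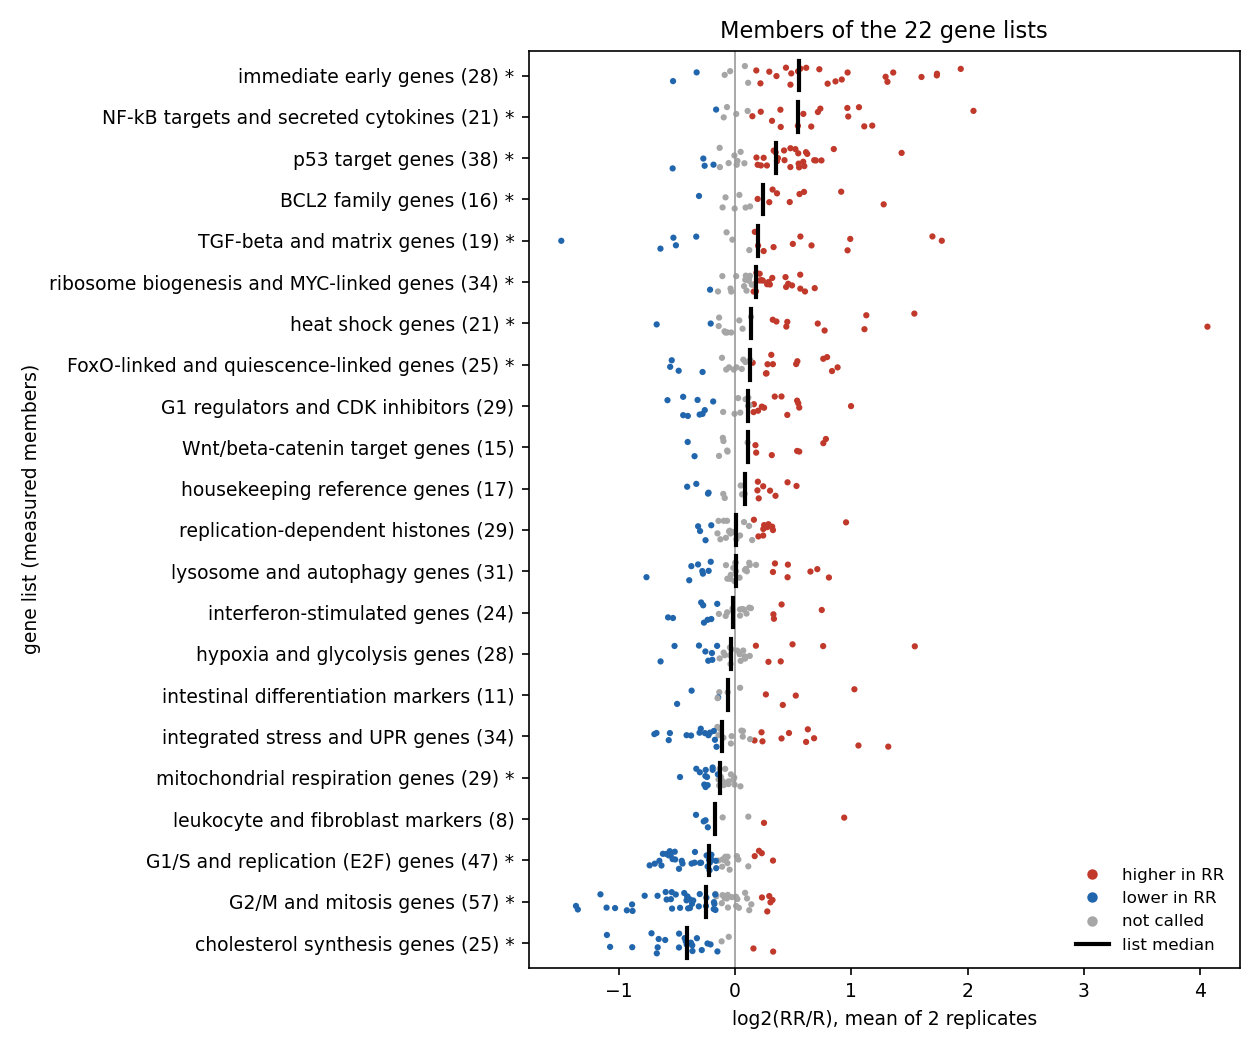
Log2 ratio of RR over R (horizontal axis, log2 units) of the measured members of each of 22 gene lists, a point per gene being the mean of the replicates (red higher, blue lower, grey not called), a black bar at the list median, and an asterisk where camera at the preset correlation called the list. With an estimated correlation camera called none of these lists, but that form could hardly call any list here. Immediate early genes had a median of 0.55 and cholesterol synthesis genes one of -0.42, while the medians of interferon and hypoxia genes, -0.02 and -0.04, turned positive under median centring.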

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

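All tests of explanations in this part were chosen after the results were seen. Of 207 list medians and genes examined over the 4 arrays, 6 had 1 array far from the other 3. For independent values chance gives about 1 in 20, or 10.35. The arrays were dye-swapped pairs of replicates, and some genes were chosen for moving the same way on all 4 arrays. The expected number is therefore only a rough guide. The ribosome biogenesis median was 0.24 on the replicate 1 array with RR in Cy5 and 0.19 to 0.20 on the others. The BCL2 family median was 0.42 on the replicate 2 array with RR in Cy3 and 0.17 to 0.21 on the others. AEN was at 0.71 on the replicate 1 array with RR in Cy5, against 0.75 on each of the others. FOXO1 was at -0.33 on that same array, against -0.55 to -0.53. TGFBI was at 1.61 on the replicate 2 array with RR in Cy5 and 1.83 to 1.85 on the others. RN7SL1, the RNA of the signal recognition particle, was at -0.54 on the replicate 2 array with RR in Cy3 and 0.11 to 0.23 on the others.

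The fall of G2/M and mitosis genes was weighed because both gates were meant to hold G1 cells. The choice of normalization as the whole cause was argued against by the list median, which stayed at or below -0.18 under 4 other scalings. All of these scalings set the centre of each array near 0, so they cannot show a shift common to most genes. Fewer S, G2 or M cells in the RR gate and a longer time in G1 would both lower the list median, and at -0.25 they cannot be told apart. The members did not fall evenly: 35 were called lower and 5 higher. The SD over members was 0.41, against a median SD between replicates of 0.15. Neither explanation was tested against this spread. The share of S, G2 and M cells in either gate is not in the values used here, and both explanations may hold.

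Immediate early genes were higher in 22 of 28 cases, NF-kB targets in 16 of 21 and heat shock genes in 10 of 21, each list with adjusted p = 0.594 with an estimated correlation. Over the 70 genes, a set with no test of its own, the median was 0.44. The choice of normalization was argued against by a median of at least 0.47 under 4 other scalings, which again cannot show a shift common to most genes. A dye bias was argued against for the joined genes by a lowest median of 0.39 on any array. For heat shock genes alone the medians were 0.31 and 0.20 with RR in Cy5, and 0.08 and 0.12 with RR in Cy3. The heat shock medians were thus smaller with RR in Cy3, but a dye bias alone would have turned them negative there. Averaging the dye-swapped arrays cancels a gene-specific dye effect, and the heat shock median was then 0.20 in replicate 1 and 0.10 in replicate 2. For the heat shock list these values argue against a dye bias as the whole cause, though not against a part in the size on single arrays. Handling of the RR cells, which were sorted a second time, replated and cultured, and a longer time in G1 differ together between the populations. At a median of 0.44 these explanations cannot be told apart, and either may account for the rise.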

How the results depend on the processing

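The fits with each gene's own spread and the replicate block forms that could be fitted were chosen after seeing the data, as were lists without single arrays. A minimum change of 1.5-fold left 442 genes higher and 377 lower, and with each gene's own spread in place of the shared one limma called 0 higher and 0 lower, with 3092 at an unadjusted p under 0.05. In both the construction explains the loss. With an estimated correlation camera called 0 lists higher and 0 lower, and fry 1 higher and 1 lower. The lists that fry called were TGF-beta and matrix genes and mitochondrial respiration genes, each at fry adjusted p = 0.0477. For the other lists called by camera, fry gave adjusted p of 0.119 to 0.261. For fry the cause was not tested. In camera, 1 residual degree of freedom estimates a correlation poorly, but the correlation was not the reason for every list. Immediate early genes had an estimated correlation of 0.0106, near the preset 0.01, yet their unadjusted camera p went from 9.5e-12 to 0.0933. That was the smallest unadjusted p of any list in this form of camera. With 1 residual degree of freedom it could hardly call a list, so its lack of calls decides nothing. In the other settings 3195 to 5249 genes or probes were higher and 3517 to 5347 lower, and median centring gave 5249 and 3517. With the replicate number as a block 4086 genes were higher and 4370 lower with a dye term, and 4429 and 4778 without it, so the block changed no count by 1.5 times. The correlation within a replicate was 0.61 with a dye term and -0.21 without it. The form without a dye term therefore did not treat a replicate's arrays as alike, and its counts do not allow for technical repeats. The block ended the calls of HSPD1 (adjusted p = 0.0629), H2AC6 (adjusted p = 0.0545) and RRM2 (adjusted p = 0.0574) without a dye term and that of MUC2 (adjusted p = 0.0868) with it. An offset of 0 ended those of CDK4 (adjusted p = 0.0605), TNFAIP2 (adjusted p = 0.0683), RRM2 (adjusted p = 0.0510) and PMVK (adjusted p = 0.0710), as did the scanner's log ratio and the deposited table. MUC2 also lost its call with no background subtraction, without the filter on dim probes, above background in both populations and with the mean over its probes, and H2AC6 with the 4 arrays as independent (adjusted p = 0.0664). The planned block with a correlation fitted beside the dye term could not be fitted on 4 arrays, and a slide block was not run because there was 1 slide. Without a replicate the values have no test. Among called lists, 9 of 12 kept their call in all of those other settings, and FoxO-linked, TGF-beta and mitochondrial genes lost it in some. Of 185 named genes 25 changed their call in some of 17 settings. H2AC6 reversed, from -0.25 to 0.22 with the mean over its probes and over a range of -0.532 to 0.0239 with 1 replicate left out. The cause was not tested. Arrays with a median signal of 112 to 229 over a background of 20.5 to 40 leave dim genes poorly measured.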

Other observations

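The tests of gene families and of small RNAs in this part were chosen after the results were seen. Families of genes sharing a name stem were scanned for shifts not covered by the lists, and of 435 families with at least 5 genes camera called 11 higher and 5 lower, with 0 called with an estimated correlation. Zinc finger genes of the ZNF family were the largest, with 194 of 369 higher and 41 lower in RR, a median log2 ratio of 0.18 and adjusted p = 6.1e-06, and adjusted p = 0.972 with an estimated correlation. ZNF425 (0.96 ± 0.07, n = 2) and ZNF35 (0.83 ± 0.00) were among them. Of 38 ZBTB genes 20 were higher and 3 lower, of 16 ZSCAN genes 11 and 0, and of 33 RBM genes 20 and 2. Of 15 SNHG genes, hosts of snoRNAs, 12 were higher and 1 lower, at a median of 0.23 and adjusted p = 0.00912, and adjusted p = 0.972 with an estimated correlation. Genes with the stem RPL, which names ribosomal proteins of the large subunit, were higher in 26 of 64 cases and lower in 1, with a median of 0.12. A stem can take in pseudogenes, which were not set apart.

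Of 30 genes with the stem KRT, which names keratins, 19 were higher and 1 lower. Camera gave a median of 0.24 and adjusted p = 0.00309, and adjusted p = 0.972 with an estimated correlation. The stem took in the pseudogene KRT16P2. It was measured only in RR, as were KRT16 and KRT17, with low bounds of 1.33-fold, 1.24-fold and 1.20-fold. KRT32 rose by 1.18 ± 0.04 (n = 2) and KRT15 by 0.76 ± 0.09. Of 8 SPRR genes, small proline-rich proteins of the epidermal envelope, 5 were higher and 0 lower, with a median of 0.52 and adjusted p = 0.0251, and adjusted p = 0.972 with an estimated correlation. SPRR1B was at 0.99 ± 0.08 and SPRR2E at 0.82 ± 0.23. The keratin-associated KRTAP3-1 was at 1.66 ± 0.06. In the other direction 10 of 12 septin genes and 6 of 6 genes and transcripts of the ANP32 group were lower, with medians of -0.23 and -0.48, as were 9 of 13 FKBP genes, at a median of -0.42 with 1 higher. These directions held under 4 other scalings.

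Of 41 small noncoding RNAs 25 were lower and 5 higher in RR, and the group was not tested as a list. Of 30 snoRNAs and scaRNAs 21 were lower and 1, SCARNA13 (0.36 ± 0.22), was higher, with a median log2 ratio of -0.41. Among 4 spliceosomal snRNAs, RNU4ATAC (1.07 ± 0.12), RNU2-2 (0.73 ± 0.22) and RNU12 (0.53 ± 0.04) rose and RNVU1-18 was at 0.04 ± 0.12 (adjusted p = 0.598). RNU4ATAC and RNU12 did not reach the filter in both populations, and their sizes depended on the processing. Over the other settings RNU4ATAC ran from 1.02 to 2.24 and RNU12 from 0.49 to 1.31. Of 7 other small RNAs 4 fell, including RN7SK (-1.01 ± 0.47) and the telomerase RNA TERC (-0.41 ± 0.20), the RNase P RNA RPPH1 rose (0.57 ± 0.54), and RN7SL1 was at -0.00396 ± 0.24.

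The choice of normalization was argued against as a cause of the fall of snoRNAs and scaRNAs, since their median stayed at or below -0.36 under 4 other scalings. These scalings cannot show a shift common to most genes. Lower recovery of all small RNA in RR remains open, because the rise of the spliceosomal RNAs, with a median of 0.63, rests on 4 RNAs. Of these, RNU4ATAC and RNU12 did not reach the filter in both populations. The size of the fall differed between replicates by a median of -0.18, and whether a different recovery of small RNA caused this cannot be told. No biological explanation of it was tested.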
